A study of Homo sapiens with 4 samples.

How the data were processed

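The series holds 4 libraries of RNA recovered by streptavidin pull-out from DU-145 cells, 2 from cells transfected with biotin-tagged, thiouridine-bearing miR-26a duplexes and 2 from cells transfected with an untagged duplex. The labels give 60 nM duplex, transfection 24 h after seeding, irradiation at 365 nm with 2 J/cm2, and 4 h of bead incubation. The series design gives the RNA input as 15 µg, and the extract protocol gives the same figure in mg. Biotin and thiouridine were present or absent together, so their effects were not separated by the design. Per the labels' protocols, TruSeq Stranded Total RNA libraries were sequenced on a HiSeq2000 as single reads of 50 bases.

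Per the submitters' processing notes, FastQC 0.10.1, cutadapt, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff were used with genome build hg38. The role and settings of each tool, the transcript annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore have been assigned to either gene. The authors deposited a Cufflinks table per library with 53209 transcript rows, and per the file headers the expression values are FPKM, fragments per kilobase of transcript and scaled to the mapped fragments of the library. Per the file headers the same tables hold the coverage of each transcript, which served here only to estimate depth. They also hold the deposited transcript length, used here to describe short transcripts and no other unit. Rows with a failed or excess-data status hold 0 that is no measurement, and the 22 genes with such a row in any library were left out of the tests.

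The tables name transcripts by RefSeq accession. Of 46699 accessions, 98.7% were given a gene symbol from the RefSeq gene table or, where that failed, from the RefSeq links of GENCODE 29. Gene FPKM was the sum over a gene's transcripts. The design fixed beforehand foresaw single transcripts if the files paired none with a gene. Since a reference table did, genes were used and single transcripts became an alternative. Positions of 24857 named genes were checked against the RefSeq table, and 98.2% lay within 1000 bp of the gene there. The 3′ UTR was that of the gene's transcript with the highest mean FPKM in GENCODE 29, or the longest where that transcript had no match. Symbols that had changed since that release were matched through Ensembl gene identifiers.

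Depth was estimated from the ratio of coverage to FPKM and the read length of 50 bases, which gave 16030000, 17840000, 17560000 and 23640000 mapped reads for control replicates 1 and 2 and biotin replicates 1 and 2. No raw counts were used, so intervals from counts are not given. Libraries of a group correlated at Pearson r = 0.971 (control) and 0.970 (biotin) across genes, which are not independent replicates, against 0.876 to 0.883 between groups.

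Tested genes had an FPKM of at least 1 in at least 2 libraries. Genes of short structured RNAs, recognised by their symbols, were left out of the tests, since a value per kilobase is unstable below the fragment length. Short transcripts without a matched symbol, NR_004406, NR_002761 and NR_030723 among them, were not recognised in this way and stayed in the tests. Biotin and control libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on log2(FPKM + 1), without further scaling, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The pseudocount of 1 understates the fold change of low genes. Residual degrees of freedom were 2 and the prior contributed 4.2. A rule of size counted genes whose FPKM + 1 was at least 2 times higher, or lower, in both biotin libraries than in either control.

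Gene sets were tested with camera at a preset inter-gene correlation of 0.01. An estimated correlation and fry were alternatives, and fry asks only whether a set's genes move on balance in a single direction. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so even a large shift is unlikely to pass. Failure there does not tell whether correlation between genes accounts for a result. The 22 gene lists, the seed site, 11 control sites, the alternatives and the rule for named genes were fixed before the data were examined. Published targets were written from memory. That rule took the 12 largest changes past the threshold per direction, every published target past it and the 5 with the largest change, up to 4 genes of each other list, and CTDSPL, CTDSP2 and EZH2. Not every gene that this rule named is described in the text.

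Alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, 3 further scalings, no variance trend, single transcripts, short RNA genes kept, the replicate number as a block, each library left out in turn, and other definitions of the seed site. A fit that leaves a group with 1 library assumes that this library varies like the others. Alternatives added after the data were seen left out the 48 genes listed at 0 in both libraries of a group, or genes with a complement of the 3′ part of miR-26a.

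limma was tested on simulated data, with 100 of 9939 genes changed 2-fold and 100 changed 4-fold in a biotin against control comparison, in 20 draws. With the moderated variances of the real genes it recovered 82.4% of 2-fold and 99.8% of 4-fold changes, and 9.27% of its calls were false. With variances drawn from the fitted prior it recovered 37.2% and 94.8%, and 5.05% of calls were false. The false share thus lay above the nominal level in the former setting. In 100 draws each, camera called 1% of unchanged sets of 36 genes and 0% of sets of 1140, and 100% of such sets raised by 0.3. Genes were drawn independently there and no gene outside the set was changed. Real sets had estimated correlations of up to 0.767, so these rates need not hold for them. Searches of 7-mers were tested on shuffled values of 9425 genes, where a planted increase of 0.2 for TACTTGA was recovered as 0.19 and ranked 1, and 0.1 was recovered as 0.08 and ranked 7. Other calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.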

Results

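RNA recovered on streptavidin was sequenced from DU-145 cells, an established line of androgen-independent human prostate cancer. The cells had been given miR-26a, a microRNA that represses mRNAs through sites matching its seed. In 2 libraries the cells received a mix of 3′-biotinylated miR-26a duplexes that carried a thiouridine at nucleotide 7 or at nucleotide 17. In the other 2 libraries they received an untagged miR-26a duplex at the same dose of 60 nM. Both groups were irradiated at 365 nm before RNA extraction, so the untagged libraries measured the RNA that stayed on the beads without a tag. The series design describes 2 biological replicates per group. From the ratio of coverage to FPKM, the control libraries held an estimated 16030000 and 17840000 mapped reads and the biotin libraries 17560000 and 23640000. At these depths 3 reads on a transcript of 1 kb corresponded to 0.187, 0.168, 0.171 and 0.127 FPKM, and such floors cover counting error only.

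The comparison of biotin with untagged pull-out asked which RNAs were recovered with tagged miR-26a. Among transcripts with a value above 0 in both groups, the largest increase was that of IGSF8, an immunoglobulin-superfamily membrane protein, from 7.42 ± 0.947 to 248.2 ± 60.9 FPKM (mean ± SD, n = 2). CLIC4, an intracellular chloride channel protein, rose from 20.0 ± 3.63 to 512.7 ± 72.7 FPKM, and SEC23A, a component of the COPII vesicle coat, from 31.5 ± 2.50 to 574.7 ± 86.8 FPKM. The log2 fold changes were 4.87 ± 0.24 (SE) for IGSF8, 4.61 ± 0.23 for CLIC4 and 4.14 ± 0.21 for SEC23A, on the log2(FPKM + 1) scale. In the other direction 17 of 18 tested genes of the replication-dependent histone list and 29 of 42 of cytoplasmic ribosomal proteins fell. Both lists passed a set test with a preset correlation (camera adjusted p = 4.9e-10 and 1.0e-09) and neither passed with an estimated correlation (camera adjusted p = 0.562 and 0.887). The latter test had only 2 degrees of freedom, so little could pass it. The correlation was estimated at 0.041 for histones and 0.246 for ribosomal proteins, against the preset 0.01. H4C12, which encodes histone H4, went from 94.6 ± 15.7 to 11.6 ± 2.87 FPKM, a log2 fold change of -2.93 ± 0.24.

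**Figure D1:**
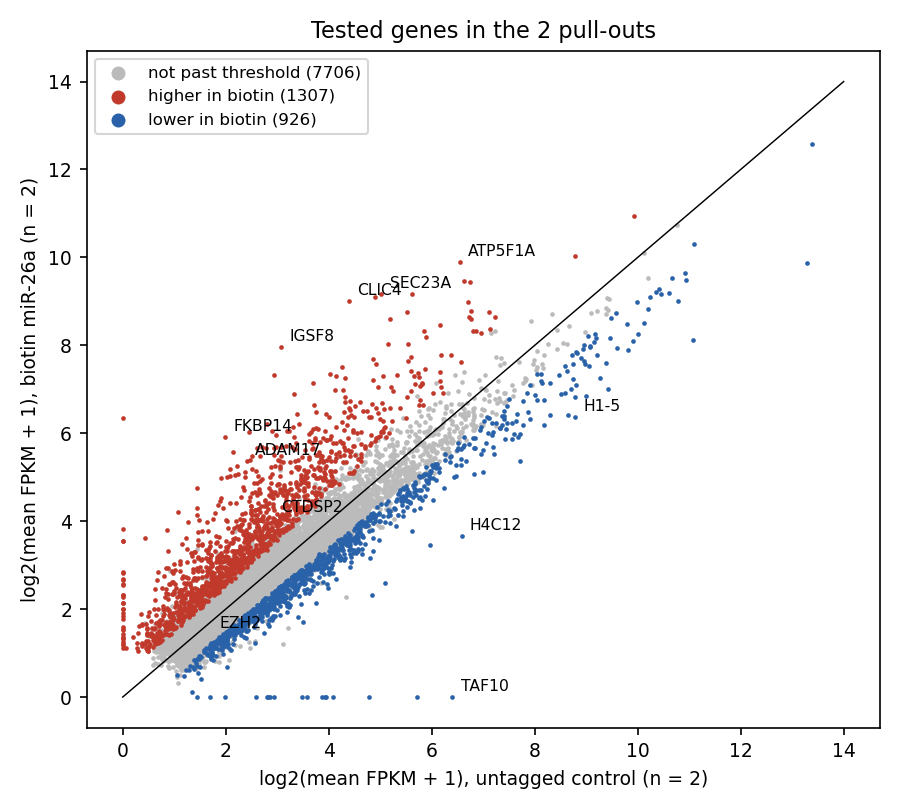
Each point is a tested gene, with the mean FPKM of the 2 control libraries on the x axis and of the 2 biotin libraries on the y axis, both as log2(FPKM + 1), and the line marks equality. The 1307 genes called higher lie above the line and the 926 called lower lie below it, and points on an axis are genes listed at 0 in both libraries of a group.

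Of 9939 tested genes, 1307 were higher and 926 lower in the biotin pull-out (limma, Benjamini-Hochberg adjusted p below 0.05, two-sided), so that 58.5% of the calls were increases. With upper-quartile scaling the split was 1224 higher and 1386 lower, or 46.9% increases. By a rule of size alone, 505 genes were at least 2-fold higher in both biotin libraries than in either control, and 120 were at least 2-fold lower. Leaving out control replicate 1 or 2, or biotin replicate 1 or 2, gave 189, 320, 626 and 680 higher genes and 32, 47, 223 and 152 lower genes. With 2 libraries per group an exact permutation test cannot go below p = 0.333, and the calls rest on limma's pooled estimate of the spread.

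Other strong increases were those of DUSP11, an RNA phosphatase (4.37 ± 0.31 on the log2 scale, ± SE), HMGN4, a nucleosome-binding protein (4.19 ± 0.21), and FKBP14, an isomerase of the endoplasmic reticulum (3.92 ± 0.16). FBXO9, an F-box protein, rose by 3.56 ± 0.26, MPV17, a protein of the inner mitochondrial membrane, by 3.56 ± 0.20, and BIRC2, an inhibitor of apoptosis, by 3.55 ± 0.18. The adjusted p of these genes lay between 0.000221 for FKBP14 and 0.000893 for FBXO9 (limma). In hg38 coordinates the transcripts with the highest FPKM were at chromosome 1, 160091339 to 160098828 for IGSF8, chromosome 1, 24745269 to 24844324 for CLIC4, and chromosome 14, 39031919 to 39103233 for SEC23A.

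Of the 12 largest increases, 3 were listed at 0 in both controls. The transcript NM_001012716 was listed at 107 and 53.0 FPKM in the biotin libraries, GNAS, which encodes a G protein subunit, at 9.77 and 16.7, and the protocadherin gene PCDHA12 at 9.95 and 11.6. Of the 12 largest decreases, 9 were listed at 0 in both biotin libraries, among them genes that all cells use. TAF10, a subunit of the general transcription factor TFIID, was listed at 84.0 and 82.6 FPKM in the controls, and RPS10, a protein of the small ribosomal subunit, at 14.1 and 13.2. The others were PTRHD1, CYB561A3, TMX2, SDR39U1, LSM1, TAF6 and ENDOG. None of these genes had a row with a failed or excess-data status. Why they were listed at exactly 0 was not tested, so no fold is given for them. In all, 31 tested genes were listed at 0 in both controls and 17 in both biotin libraries, and all 48 were among the calls. Besides H4C12, the remaining decreases were the short transcripts NR_004406, of 205 nt, and NR_002761, of 138 nt, for which values per kilobase are unstable. NR_004406 was listed at 7362 and 12552 FPKM in the controls and 700.5 and 1173 in the biotin libraries, and NR_002761 at 2459 and 1824 against 318.5 and 234.2.

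Published targets of miR-26 were the second question, with a list of 50 genes written before the data were examined. Of 36 tested targets, 6 rose and 0 fell in limma, and 30 did not pass the test; adjusted over the list alone, 5 rose. At an unadjusted p below 0.05, 11 of the 36 were up, those 6 included, and 3 were down. Over all 9939 tested genes, 3914 had an unadjusted p below 0.05 in either direction (limma), and 1307 were called higher. Such calls were thus frequent among all genes and not only among targets. ADAM17, a sheddase of membrane proteins, rose from 4.31 ± 0.41 to 40.3 ± 8.74 FPKM (n = 2), a log2 fold change of 2.95 ± 0.21 with an adjusted p of 0.000793 (limma). CTDSP2 and CTDSPL, phosphatases whose genes host the miR-26a precursors, rose by 1.16 ± 0.17 and 0.94 ± 0.16. The anti-apoptotic gene MCL1 (0.98 ± 0.27), the RNA-binding protein gene LARP1 (0.95 ± 0.17) and the replication licensing gene CDC6 (0.79 ± 0.15) were the other increases. EZH2, the Polycomb methyltransferase, was at 2.28 ± 0.33 FPKM in control and 1.67 ± 0.33 in biotin libraries (log2 fold change -0.30 ± 0.16, adjusted p = 0.227, limma). As a set, the targets lay 0.23 above the other genes on the log2 scale, which did not pass the threshold (camera p = 0.0561 and adjusted p = 0.248 over 18 lists; adjusted p = 0.924 with an estimated correlation). ADAM17 passed in all 4 fits with a library left out, and the other 5 targets each lost the call in at least 1 of them. A filter for a mean FPKM of at least 5 used all 4 libraries, and so the values under test. ADAM17, CTDSPL and CDC6, at 4.31, 3.60 and 4.10 FPKM in the controls, were kept through their biotin values. The set passed under that filter (0.62 for 15 targets, camera adjusted p = 0.0168 over the lists), but the filter favours targets that rose. At an unadjusted camera threshold of 0.05 it also passed without control replicate 2, at 0.26, and without biotin replicate 1, at 0.31.

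**Figure D2:**
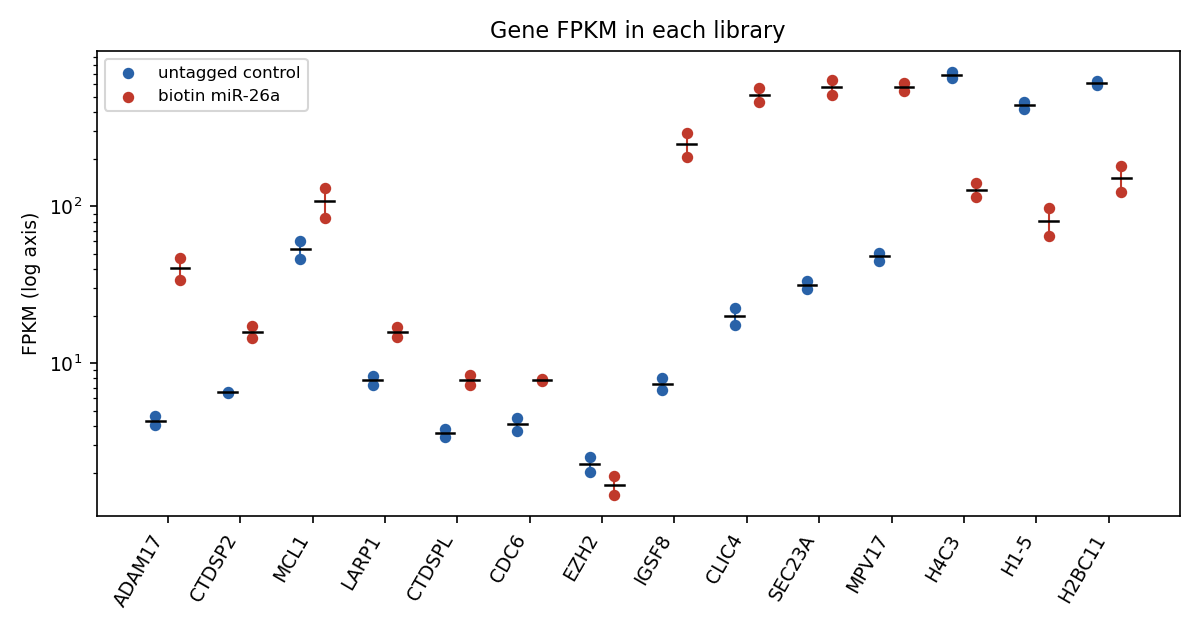
Points are the FPKM of single libraries on a log axis, blue for the 2 untagged controls and red for the 2 biotin libraries, and black bars are group means. ADAM17 reached 34.2 and 46.5 FPKM in the biotin libraries against 4.02 and 4.60 in the controls, while H4C3, H1-5 and H2BC11 were lower in both biotin libraries.

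Seed sites were searched in the 3′ UTRs of 9425 tested protein-coding genes. The site TACTTGA, complementary to miR-26a nucleotides 2 to 8 counted from its 5′ end, occurred in 1141 of them. Genes with a site rose in 14.4% of cases and genes without in 12.96%, and their mean log2 fold changes differed by 0.06, which camera did not call (p = 0.438; 0.771 with an estimated correlation). The median was -0.04 with a site and -0.07 without. After adjustment for 3′ UTR length and GC content the difference was 0.07 ± 0.02 (SE across genes, which are not independent replicates). It ranked 1 by its ratio to its error among the 420 reorderings of the same bases. None of 11 control sites passed either, and the lowest adjusted p was that of miR-34a (camera adjusted p = 0.139 over the 12 sites). Before adjustment the difference was larger than for miR-26a with miR-34a (0.14), miR-29 (0.11), miR-16 (0.11), let-7 (0.10) and miR-124 (0.08) sites. It was smaller for the other control sites, and after adjustment it was smaller for all 11. ATP5F1A, CHAC1 and ADAM17 were named genes with a site that rose, by 3.34 ± 0.19, 2.34 ± 0.25 and 2.95 ± 0.21, while TTK and HSPA8 had a site and fell by 0.97 and 0.95 on the log2 scale. No site was found in the 11 searched genes among the 12 largest increases, nor in CTDSP2 and CTDSPL, which rose.

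Of 18 fixed gene lists large enough to test, 3 passed the threshold, and each was lower in the biotin pull-out. Replication-dependent histones, made in S phase from mRNAs without a poly(A) tail, fell in 17 of 18 tested members and rose in 0. H1-5 fell from 440.2 ± 31.8 to 81.1 ± 23.2 FPKM, H4C3 from 686.8 ± 45.1 to 127.3 ± 18.2 and H2BC11 from 613.7 ± 27.1 to 151.8 ± 39.5. The list lay at -1.67 relative to the other genes (camera adjusted p = 4.9e-10; adjusted p = 0.562 with an estimated correlation). Cytoplasmic ribosomal proteins fell in 29 of 42 members, among them RPL12 (-1.59 ± 0.25) and RPL35 (-1.50 ± 0.26), while RPL15 rose from 137.9 ± 43.2 to 428.9 ± 175.1 FPKM. That list lay at -0.88 (camera adjusted p = 1.0e-09; adjusted p = 0.887 with an estimated correlation). Adjusted over the list alone, 34 ribosomal protein genes fell. Nuclear-encoded oxidative phosphorylation genes fell in 9 of 30 members, among them NDUFA1 of complex I (-1.22 ± 0.24) and ATP5PO of ATP synthase (-1.12 ± 0.19). ATP5F1A, the alpha subunit of ATP synthase, rose from 92.7 ± 3.92 to 950.4 ± 75.4 FPKM. This list lay at -0.40 (camera adjusted p = 0.0120; adjusted p = 0.887 with an estimated correlation), and adjusted over the list alone 14 fell and 2 rose. Tested against no change rather than against other genes, histones passed at a mean log2 fold change of -1.63 (fry adjusted p = 0.0409). Ribosomal proteins at -0.83 and oxidative phosphorylation genes at -0.36 did not pass that test (fry adjusted p = 0.108 for both). Under upper-quartile, median-of-ratios and quantile scaling 17, 16 and 14 histones fell, 33, 28 and 18 ribosomal protein genes, and 12, 8 and 10 oxidative phosphorylation genes, and the median of each list was below 0 under each scaling. Histone genes resemble each other closely and ribosomal protein genes have many pseudogenes, so the values of single members are uncertain where reads could be divided among copies. With a library left out, H4C3 and ATP5F1A passed in all 4 fits, and each other gene named for these 3 lists lost its call in at least 1, among them RPL15 without control replicate 1 (adjusted p = 0.144, limma).

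**Figure D3:**
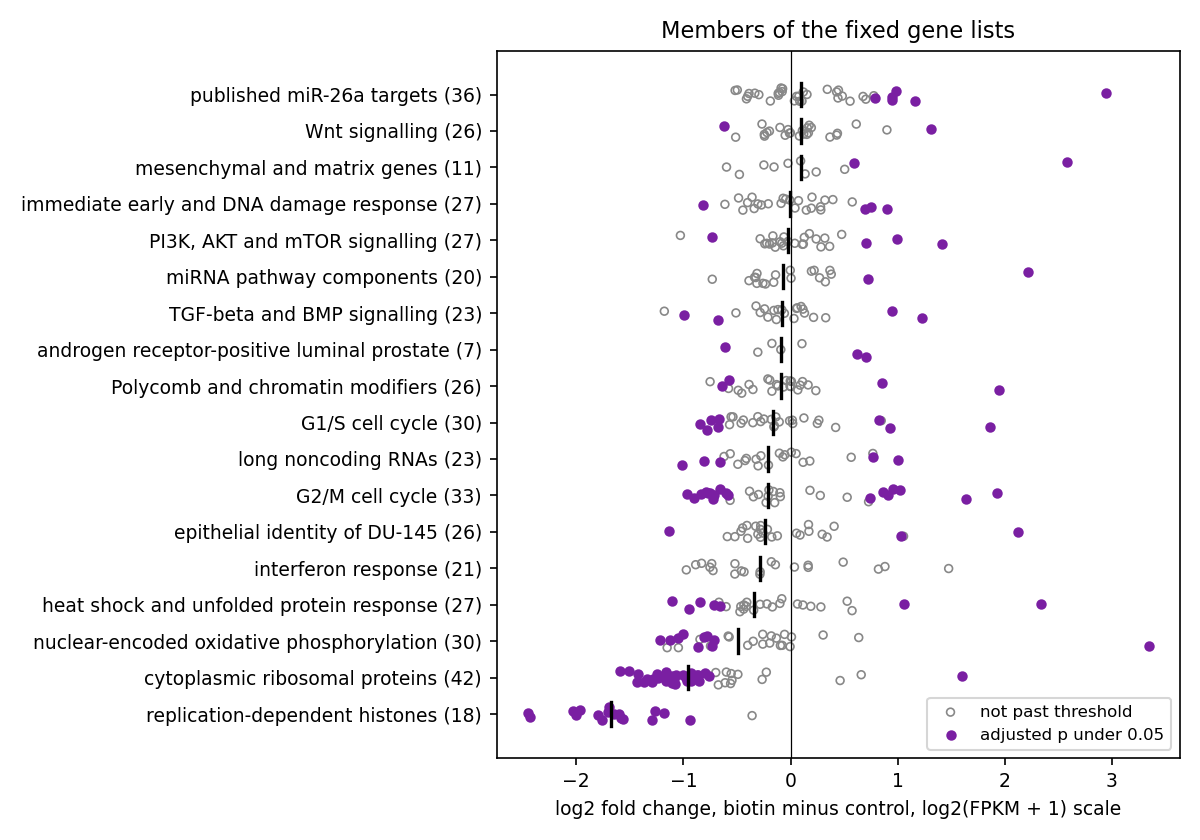
Each point is a tested gene of a fixed list, placed by its log2 fold change of biotin minus control libraries (n = 2 each), filled where its adjusted p was below 0.05, and bars are list medians, with the number of genes in parentheses. Histones have a median of -1.67 and ribosomal proteins of -0.96, and single genes such as ATP5F1A stand apart from their list.

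The remaining lists did not pass as sets. Over all 9939 tested genes 1307 rose and 926 fell, and the counts per list here and below are to be read against that. Among miRNA pathway components 2 of 20 rose and 0 fell: XPO5, which exports miRNA precursors from the nucleus, by 2.22 ± 0.18, and the deadenylase subunit PAN2 by 0.72 ± 0.15, while AGO2 was at 12.5 and 9.29 FPKM (control and biotin means). Of G1/S genes 3 of 30 rose and 5 fell, with MCM3, a subunit of the replicative helicase, at 1.86 ± 0.18. Of G2/M genes 7 of 33 rose and 11 fell, with the ubiquitin-conjugating enzyme UBE2C at 1.93 ± 0.37 and the mitotic kinase TTK at -0.97 ± 0.16. Adjusted over each list alone these counts were 4 and 7 for G1/S and 8 and 12 for G2/M, and 1 and 0 for Wnt signalling; those of the other lists in this paragraph were as over all genes. Polycomb and chromatin modifiers rose in 2 and fell in 2 of 26, with the deacetylase HDAC1 at 1.95 ± 0.21. In PI3K, AKT and mTOR signalling 3 of 27 rose and 1 fell, with the transcription factor FOXO3 at 1.41 ± 0.19. In TGF-beta and BMP signalling 2 of 23 rose and 2 fell, with the receptor ACVR1B at 1.23 ± 0.13. In Wnt signalling 1 of 26 rose, the inhibitor DKK1 at 1.31 ± 0.17, and 1 fell, the receptor FZD6 at -0.62 ± 0.17. With a library left out, XPO5 passed in all 4 fits, and the other genes of this paragraph with a call lost it in at least 1.

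Heat shock and unfolded protein response genes rose in 2 and fell in 5 of 27, with the glutathione-degrading enzyme CHAC1 at 2.34 ± 0.25 and the chaperone HSP90AA1 at -1.11 ± 0.19. Immediate early and DNA damage genes rose in 3 and fell in 1 of 27, with SESN2 at 0.90 ± 0.15 and FOS at -0.82 ± 0.16. Of 21 interferon response genes 0 passed in limma (1 up and 2 down at an unadjusted p below 0.05), and IRF9 was listed at 5.13 and 1.78 FPKM in the controls and 14.9 and 7.28 in the biotin libraries. As a set they lay at -0.21 (camera adjusted p = 0.636; adjusted p = 0.924 with an estimated correlation), and 20 of the 21 were higher in replicate 1 than in replicate 2 of both groups. Leaving out a library unbalances that difference. At the preset correlation the set passed without control replicate 2 (-0.72, camera adjusted p = 0.0444) and without biotin replicate 1 (-0.71, camera adjusted p = 0.0331), and it lay at 0.30 and 0.28, without passing, when control replicate 1 or biotin replicate 2 was left out. The correlation between these genes was estimated at 0.767 with all 4 libraries, far above the preset 0.01. Long noncoding RNAs rose in 2 and fell in 3 of 23, with SNHG8, whose main transcript is 274 nt long, at 1.00 ± 0.22 and SNHG6 at -1.01 ± 0.21; adjusted over the list alone, 4 fell. Each called gene named in this paragraph lost its call in at least 1 of the 4 fits with a library left out.

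Markers of cell identity were also compared. Of the epithelial genes of DU-145, 2 of 26 rose, the hyaluronan receptor CD44 (2.12 ± 0.20) and the growth factor receptor EGFR (1.03 ± 0.18), and 1 fell, S100A6 (-1.14 ± 0.22). Mesenchymal and matrix genes rose in 2 of 11, with the actin-binding protein TAGLN at 2.58 ± 0.21. Of 7 tested genes of androgen receptor-positive luminal prostate 2 rose and 1 fell, STEAP1 at -0.61 ± 0.16. Blood cell markers had 3 tested genes, of which CD14 rose and CD74 fell, and neuroendocrine markers had 1, ENO2, which rose. Both lists were below the minimum of 5 genes for a set test, and mitochondrially encoded genes were not analysed here. For the androgen receptor-positive and immediate early lists the camera direction was up although the mean difference and the median were below 0. For the miRNA pathway and PI3K lists the camera direction and the mean difference were up and the median was below 0. Adjusted over the list alone, the counts in this paragraph were as over all genes. CD44 and TAGLN passed in all 4 fits with a library left out, and the other called genes of this paragraph lost the call in at least 1.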

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

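Short RNA genes were outside the tests of the report, and 36 of the 286 with an FPKM of at least 1 in 2 libraries were at least 2-fold higher in both biotin libraries than in either control. Of these 36, 27 were listed at 0 in both controls, without a failed or excess-data status, and the reason for these values of 0 was not tested. A further 54 were at least 2-fold lower, 4 of them listed at 0 in both biotin libraries. Among those with values above 0 in every library, SNORD83A, a box C/D small nucleolar RNA, was listed at 29.7 and 25.2 FPKM in the controls and 235.9 and 278.9 in the biotin libraries, and SNORD25 at 100.8 and 152.0 against 306.7 and 313.1. They drew attention because the signal lay above the controls in data the comparisons did not use. No explanation was tested for these values.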

How the results depend on the processing

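Leaving out genes listed at 0 in both libraries of a group, and leaving out genes with a complement of the 3′ part of miR-26a, were chosen after seeing the data. Each leave-one-out fit left a group with 1 library, assumed to vary like the others. The 2-fold rule then compared the kept libraries only, so "both biotin libraries" in the ranges that follow stands for those kept. Leaving out a library can only loosen that rule. Its counts could therefore not fall below the 505 higher and 120 lower genes found with all 4 libraries, and their rise does not test stability. Over these fits the higher genes ranged from 189 to 680, the lower genes from 32 to 223, the genes at least 2-fold higher in both biotin libraries from 589 to 693 and those 2-fold lower from 171 to 259, and the published targets' difference from 0.16 to 0.31. Without a filter on low values 653 genes were higher and 230 lower, with 16113 genes tested. Single transcripts gave 336 and 142, and 779 and 316 by the 2-fold rule. A pseudocount of 5 gave 279 and 77 by that rule, since it shrinks low genes. Among genes with a mean FPKM of at least 5 the published targets passed (0.62 for 15 genes). That filter used the biotin values too and so favours targets that rose. With an estimated correlation, on 2 residual degrees of freedom, 0 gene lists passed, and with fry 1. Across all tested genes the deviations of libraries with the same replicate number were uncorrelated (0.0024). That does not exclude a shared effect on some genes, since 20 of 21 interferon genes were higher in replicate 1 of both groups. A replicate block gave 1078 higher and 534 lower genes. Upper-quartile scaling turned the balance of calls to 1224 higher and 1386 lower. The cause of these shifts was otherwise not tested. Over the alternatives, 19 values of 6 gene lists and 3 values of named genes had the other sign than in the main fit. Of these, 0 passed either in that alternative or in the main fit. The interferon list was among the 6, at 0.30 without control replicate 1 and -0.72 without control replicate 2. Of 84 named genes past the threshold, 30 passed in all 4 leave-one-out fits, 54 lost the call in at least 1, and 0 changed sign. The seed-site difference did not pass in any alternative run and ranged from 0.01 to 0.15. Without genes listed at 0 in both libraries of a group there were 1269 higher and 900 lower genes. Depths of 16030000 to 23640000 reads and 2 libraries per group limit what low genes can show.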

Other observations

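All tests on complements of miR-26a below were chosen after the fold changes had been seen; those on histones and ribosomal proteins were written before their results, and were repeated once after older gene symbols had been matched, which brought every tested member in.

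Several abundant structured RNAs, which were not tested, had lower values in both biotin libraries than in either untagged library. RMRP, the RNA of RNase MRP, was listed at 343704 and 289785 FPKM in the controls and 44569 and 38499 in the biotin libraries. RN7SK, which restrains transcription elongation, was at 162887 and 109540 against 18866 and 17895, and RPPH1, the RNA of RNase P, at 111615 and 48403 against 8122 and 7470. RN7SL1 and RN7SL2 were listed at 0 in both controls, had rows with a failed or excess-data status, and were not compared. Without the genes listed at 0 in a group, a selection made after the values were seen, the largest decreases were those of NR_004406, NR_002761 and H4C12, followed by other histone genes, H4C13, H4C11 and H2AC4 among them, and the short transcript NR_030723.

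Enriched transcripts carried complements of the 3′ part of miR-26a. Over 16323 7-mers in 3′ UTRs, adjusted for length and GC content, the strongest increase went with GCCTGTC (0.29 ± 0.02 on the log2 scale, SE across genes, 1016 genes), which pairs nucleotides 15 to 21 with the change A17G. Positions count from 1 at the miRNA's 5′ end, and the token gives the complementary base, the nucleotide and the base of the site. The seed site TACTTGA ranked 99. Genes with a complement of at least 9 nt to nucleotides 11 to 22 anywhere in the transcript, with A or G opposite 17, numbered 1351. After adjustment for transcript length and GC content they lay 0.63 ± 0.02 above the others. They made up 43.7% of the genes that rose, 9.89% of those that did not and 1.85% of those that fell, and 31 of the 50 largest increases. For complements of nucleotides 1 to 11 anywhere in the transcript, the share of genes that rose was 13.2% at 4 to 6 nt. At 7, 8 and 9 nt it was 12.7%, 13.17% and 13.75%, and at 10 nt 22.02% of 109 genes. At 11 nt 0 of 9 genes rose.

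A candidate explanation is that RNA paired with the tagged strand outside its seed. The share of genes that rose went up with the longest complement, from 4.14% at 4 to 6 nt over 6.38%, 14.8%, 33.7% and 53.7% at 7, 8, 9 and 10 nt to 72.0% of 75 genes at 11 or 12 nt. Length and base composition are argued against, since the highest of 100 reordered sites reached 0.0941. The reordered sites were drawn at random, whereas the site itself was chosen after the fold changes had been seen. Capture of either strand is argued against too, since the reverse complement reached 0.0216 ± 0.0221. Sites with A17G lay 0.1003 ± 0.0241 above sites with the complementary A in a joint model, which restates the scan of 7-mers on the same genes, so that a preference for G opposite the thiouridine stays open, and at nucleotide 7, the other thiouridine, A7G lay at 0.0777 ± 0.0165 and the complementary A at 0.0963 ± 0.0171. Whether pairing took place in cells or during the pull-out stays open, and the tag and the thiouridine cannot be separated in these libraries.

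Sites outside the 3′ UTR went with increases too. Compared with genes without a site, the adjusted difference was 0.64 ± 0.02 for 671 genes with sites in the coding sequence alone, 0.61 ± 0.03 for 543 with sites in the 3′ UTR alone and 0.51 ± 0.07 for 70 with sites in the 5′ UTR alone. Of the 11 genes with a searched transcript among the 12 largest increases, 8 had a complement of at least 9 nt, while the longest in FBXO9, GNAS and PCDHA12 was 7 nt. BIRC2 and MPV17 had complements of 10 nt in the coding sequence, CCTATCCTGG and CCTGTCCTGG, and IGSF8 and DUSP11 had CCTGTCCTGG in the 3′ UTR. These genes were picked for their increase, so their sites are given as a description and not as a test.

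Histone and ribosomal protein mRNAs are short, with medians of 540 and 886 nt. Set against 5 genes each of matched length and GC content, histones still lay at -1.44 ± 0.161 and ribosomal proteins at -0.618 ± 0.0991, which argues against length and GC content as the whole cause. A lack of complements to the 3′ part is argued against as the whole cause as well. Among genes without an 8-nt complement, 17 histones lay at -1.5 ± 0.123 and 32 ribosomal protein genes at -0.76 ± 0.0805 relative to the others. That comparison was not matched on length and GC content, so both explanations together were not tested. The errors in this paragraph are SE across genes, which are not independent replicates. No biological explanation was tested, and the abundance of these RNAs on untagged beads stays open.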
